A study of Mus musculus with 12 samples.

How the data were processed

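Gene expression was measured on Illumina mouse bead arrays with RNA of microdissected diencephalon of CD1 embryos at E12.5. Per the labels, RNA was extracted with TRIzol and column clean-up, checked on a Bioanalyzer and amplified to biotin-labelled cRNA. The 12 arrays lie on 2 chips, and groups and replicate numbers were taken from the labels. The labels exclude replicate 5 of each genotype as an outlier, and these 2 arrays entered only an alternative and checks named as such.

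The deposited unnormalized tables give a bead intensity per probe and array on a linear scale, with no normalization and no error model by the scanner software, per the file headers. Per the file headers the software was GenomeStudio, and the submitters' processing notes name BeadStudio, GenomeStudio and lumi without saying what each did. The detection columns hold a fraction between 0 and 1, per the file headers a detection score or p-value. On both chips bright probes lie near 1, so the detection p was taken as 1 minus that fraction. The deposited normalized tables hold log2 values, and the method that made them is not given in the sources used here. In those log2 values the probe means of the chips differ by a median of 0.02, against 0.37 in the unnormalized signals, so the chips were adjusted to each other in the deposited tables. The column medians of the deposited log2 values lie between 7.14 and 7.16.

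The tables hold 46147 probes on chip 1 and 45281 on chip 2. A deposited table joins 31459 probes over the chips. Of these, 31448 were found by their signals on both chips and used, and 11 whose chip 1 value was a mean were left out. Names were updated through a gene table of assembly GRCm38.p6, used for names only: 19540 probes by accession, 2780 by current symbol and 2318 by synonym, with 6821 kept under the name of the file. The probes used stand for 23397 genes. Chip 2 holds 13822 probes outside the joined table. After a detection filter, 6879 probes without a partner in use on chip 1 were tested on chip 2 alone. Their p-values were adjusted among all 21369 chip 2 probes tested.

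Signals were processed per chip with neqc of limma 3.58.1 in R 4.3.3: normexp background correction by detection p, an offset of 16, quantile normalization and log2. Probes detected at p under 0.05 on at least 4 of the 8 arrays were kept, and each gene was represented by its probe with the highest mean over the 8 arrays. KO and WT were compared with limma's lmFit and eBayes, with chip as a block, two-sided, and Benjamini-Hochberg adjustment at 0.05. A gene not detected on any array of a group has only a bound there. Its fold is given as at least N-fold, from the mean of the brighter group against, per array, the higher of the lowest detected signal and the gene's own. The arrays' number limits the precision, and signal over background limits what can be seen of dim genes: maximum signals were 37004.8 to 51355.8 on chip 1 and 72239.3 to 73550.2 on chip 2.

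Before the data were examined, 23 gene lists were fixed: postmitotic caudal thalamus, habenula, epithalamic midline, prethalamic and GABAergic, rostral thalamus and zona limitans, progenitors, cell cycle, pan-neuronal, axon guidance, cadherins, pretectum and midbrain, Sonic hedgehog, Wnt and p53 targets, dissection stress, blood, endothelium, meninges, microglia, choroid plexus, telencephalon, hypothalamus, and Y-linked genes with Xist. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. They were tested again with an estimated correlation, with which none of the lists was called. That second setting weakens calls by more than the correlation. The habenular list, with an estimated correlation of only 0.0058, went from a camera adjusted p of 0.00818 to 0.324. A call lost there thus does not by itself show that the members move together. The epithalamus and prethalamus have 1 array each, so genes were counted where the log2 difference was 1 or more in size, in 1 direction, against both WT thalamus arrays of chip 1, without a test. The sets so found were tested with camera on chip 2 alone.

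Genes to be named were set by a rule fixed at the same time: Gbx2, the 12 largest rises and the 12 largest falls among genes past the threshold and separated on both chips, and up to 4 members of each list past the threshold or the 2 with the smallest p. For each region the rule took the 8 largest differences in each direction and the 3 largest of 4 lists. Clone names were passed over. Genes named outside the rule are said to have been picked after their values were seen.

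The procedure was tested on simulated data of 10384 genes for 4 against 4 arrays. Of 100 genes changed 2-fold 59 were recovered, and of 100 changed 4-fold 91, with 10 false calls. A list of 14 genes shifted by 0.8 was called and 0 unchanged lists were. The simulated noise was independent between genes, so it does not test false list calls where members move together. In the data the estimated correlation of the cell cycle list was 0.837. No arrays were duplicates, since at most 0.362% of signals were identical between any pair. Alternatives covered the normalization, the deposited values, the offset, the filter, the excluded arrays, the block, array weights, the variance model, the probe rule, each chip alone and leaving out each array. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.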

Results

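RNA from microdissected thalamus of wild-type (WT) and Gbx2 knockout (KO) mouse embryos at E12.5 was hybridised to Illumina bead arrays. Gbx2 encodes a homeobox transcription factor of the caudal thalamus, and the series title frames the work around the part Gbx2 plays in thalamic neuron identity and in holding back habenular features. The series holds 12 arrays of CD1 embryos on 2 chips, which stand under 2 platform records and carry different probe sets. Chip 1 carries WT thalamus replicates 1 and 2, KO thalamus replicates 1 and 2, 1 array of WT epithalamus and 1 array of WT prethalamus. Chip 2 carries WT and KO thalamus replicates 3, 4 and 5. The labels mark replicate 5 of each genotype as an excluded outlier, so 4 WT and 4 KO thalamus arrays enter the comparison of genotypes. The tissue field of the labels reads thalamus for every array, and the epithalamus and prethalamus arrays were placed by their description. Between 30.7% and 36.04% of the probes were detected on the arrays of chip 1, and between 44.8% and 46.4% on those of chip 2. The labels do not say whether an array holds RNA of 1 embryo or of several, so p-values measure the spread between these samples. The number of arrays limits the precision of every value.

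Gbx2 was lower on the KO arrays of each chip than on the WT arrays of that chip. Its log2 intensity was 13.73 and 13.30 on WT replicates 1 and 2 against 13.04 and 12.77 on KO replicates 1 and 2. On chip 2 it was 15.94 and 15.73 on WT replicates 3 and 4 against 13.76 and 14.05 on KO replicates 3 and 4. With chip as a block, Gbx2 fell by 1.27 on the log2 scale (SE 0.27, n = 4 per genotype, limma adjusted p = 0.0407), with differences of -0.62 on chip 1 and -1.93 on chip 2. On chip 2 the signals of WT replicates 3 and 4, 66719.6 and 57517.7, lay near the array maxima of 73208.2 and 72270.9, so the difference there may be compressed. Gbx2 stayed bright on the KO arrays, where 137 and 174 probes were brighter on KO replicates 1 and 2, and 556 and 442 on KO replicates 3 and 4. The epithalamus array, by contrast, read 6.35 and the prethalamus array 8.27. Whether the single Gbx2 probe lies in the deleted part of the gene is not known here, and a probe outside it would not check the labels. On chip 1 alone Gbx2 did not pass the test (adjusted p = 0.496), and leaving out KO replicate 1, 2, 3 or 4 or WT replicate 3 or 4 gave adjusted p values of 0.0602, 0.0796, 0.0989, 0.103, 0.107 and 0.139.

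Transcripts of Cyp1b1, Ntng1, Id4 and Rora were lower in the KO thalamus than in WT, and those of Shisa2, Angpt1 and Mcm10 were higher. Of genes past the threshold and named by the rule, the largest fall was that of Cyp1b1, a cytochrome P450. Cyp1b1 was below background on all 4 KO arrays and at least 19.5-fold lower than in WT. Ntng1, which encodes the axonal membrane protein netrin-G1, was 9.02-fold lower by the probe used. In log2 that probe stood at -3.17, another joined probe at -1.67, and probes on chip 2 alone at -3.21 and -3.68. Id4, an inhibitor of basic helix-loop-helix transcription factors, was 9.13-fold lower. Among genes past the threshold and named by the rule, the largest rise was that of Shisa2, which was 5.17-fold higher. Shisa2 is an endoplasmic reticulum protein that restrains Wnt and FGF receptors. Of 10384 genes tested, 298 changed at an adjusted p under 0.05, with 144 higher and 154 lower in the KO.

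Further large falls were those of Kirrel3, Nxph1, C1ql2 and Pdzrn4. Kirrel3, an immunoglobulin superfamily adhesion molecule, fell by 3.58 (SE 0.29, adjusted p = 0.000631). The neurexophilin gene Nxph1 fell by 3.28 (SE 0.52, adjusted p = 0.0173), and C1ql2, a secreted C1q-like protein, fell by 3.64 (SE 0.47, adjusted p = 0.00816). Nxph1 was detected on 2 of 4 KO arrays and C1ql2 on 1 of 4, so these sizes rest in part on KO values at background. Pdzrn4, a PDZ and RING domain gene, fell by 3.60, with its 3 other joined probes at -2.91, -2.07 and -0.28, and the phosphatase gene Ppm1h fell by 3.17. Id4 and Sertad4 shared the smallest adjusted p, 0.000352, with log2 fold changes of -3.19 (SE 0.21) and -3.00 (SE 0.20). Samd5 fell by 2.85 (SE 0.26). Rora, a nuclear receptor gene of thalamic neurons, fell by 2.99 (SE 0.43, adjusted p = 0.0116). Calb2, which encodes calretinin, was at least 5.01-fold lower by the probe used (adjusted p = 0.0286), which was below background on every KO array. A further Calb2 probe, on chip 2 alone and detected on both KO arrays there, fell by 4.88.

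The 12 largest rises included Mcm10, Rrm1, Ect2, Asf1b and Fanci. Mcm10, a replication factor, was 3.90-fold higher (adjusted p = 0.0241), and Rrm1, the large subunit of ribonucleotide reductase, was 3.38-fold higher (adjusted p = 0.0223). Ect2, which acts in cytokinesis, was 3.72-fold higher, the histone chaperone gene Asf1b 3.50-fold and the Fanconi anaemia gene Fanci 3.52-fold. Shcbp1 was 3.27-fold higher by the probe used, with an adjusted p of 0.0446, but another joined probe stood at 0.26 in log2 against 1.71. On the excluded WT replicate 5 the mean of the fixed cell cycle genes stood at 1.71 above the kept WT arrays of its chip. Angpt1, a ligand of the Tie2 receptor, was 4.52-fold higher, and the LIM-only gene Lmo3 3.98-fold. The medium neurofilament gene Nefm was 3.23-fold higher, the type II collagen gene Col2a1 3.21-fold and Pdlim1 3.08-fold.

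All 298 genes, which the joint test picks for such a pattern, had every KO array beyond every WT array of the same chip. Chance alone would separate 2.78% of genes in a given direction on both chips, and among all tested genes 1069 were separated upwards and 1014 downwards. The count depends on which arrays are used: it was 612 without WT replicate 1, 109 without WT replicate 2, 105 without WT replicate 3 and 69 without WT replicate 4, and 63, 86, 140 and 82 without KO replicates 1, 2, 3 and 4. With the excluded replicate 5 of each genotype included, 15 genes passed.

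**Figure D1:**
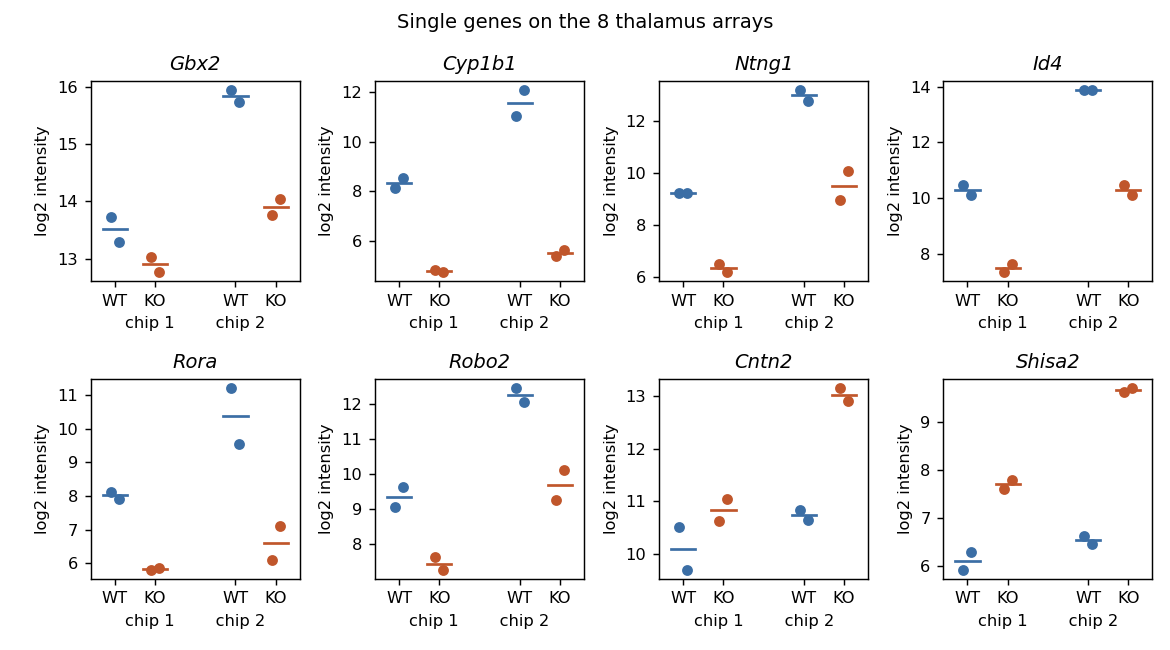
Log2 intensity (vertical axes) of 8 genes on the WT (blue) and KO (orange) thalamus arrays of chip 1 and chip 2, with 1 point per array and a line at the mean of the 2 arrays. On both chips the KO points of Gbx2, Cyp1b1, Ntng1, Id4, Rora and Robo2 lie under the WT points, and those of Cntn2 and Shisa2 lie above them.

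Genes of postmitotic caudal thalamic neurons split in direction. Of 14 measured members, Ntng1, Calb2 and Rora fell, Cdh6 rose by 1.09 (SE 0.19, adjusted p = 0.0229) and 10 did not pass the test. Adjusted over the list alone, 5 were lower and 4 higher. Members that did not pass, picked here after their values were seen, include the zinc finger gene Zic4 at 2.79 (SE 0.73, adjusted p = 0.0779), the largest in size, Lhx9, a LIM homeobox gene, at 0.06 (SE 0.15), the vesicular glutamate transporter gene Slc17a6 at -0.19 (SE 0.15) and Foxp2 at -0.79 (SE 0.18, adjusted p = 0.0532). The list as a whole was not called (camera adjusted p = 0.449, and adjusted p = 0.643 with an estimated correlation).

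Habenular and epithalamic midline genes were shifted upwards as lists, though few single members passed. Among 11 measured habenular genes, Cntn2, an axonal adhesion molecule, rose by 1.51 (SE 0.32, adjusted p = 0.0413), and 9 of the 11 had positive values. The habenular list had a median log2 fold change of 0.63 and a camera adjusted p of 0.00818, with an adjusted p = 0.324 with an estimated correlation. Adjusted over the list alone, 5 habenular genes passed. Of 9 measured roof plate, epithalamic progenitor and pineal genes, the Wnt potentiator gene Rspo1 rose by 1.42 (SE 0.22, adjusted p = 0.0163). That list had a median of 0.89, 5 members past the threshold adjusted over the list alone, and a camera adjusted p of 0.000613, with an adjusted p = 0.324 with an estimated correlation. Values that did not pass, picked after they were seen, include Rspo3 at 2.25 (SE 0.66) and the zinc finger genes Zic1 at 1.11 (SE 0.42) and Zic2 at 1.32 (SE 0.49). Also picked after the values were seen, Irx2, a habenular gene with probes on chip 2 only, stood at 2.43, 2.20 and 1.82 by its 3 probes there, of which 1 passed (adjusted p = 0.0289), and a chip 2 probe of the habenular POU domain gene Pou4f1 at 1.87 (adjusted p = 0.0836). In the other direction Wif1, picked in the same way and of the same list, with a probe on chip 2 only, fell by 2.62 (adjusted p = 0.0243). With the excluded replicate 5 arrays included, the midline list was not called (camera adjusted p = 0.236), while the habenular list was (camera adjusted p = 0.000366).

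All 14 measured proliferation genes had positive values. The replication licensing gene Mcm5 rose by 1.38 (SE 0.31), the survivin gene Birc5 by 1.14 (SE 0.19), the thymidylate synthase gene Tyms by 1.08 (SE 0.19) and the topoisomerase gene Top2a by 0.96 (SE 0.20), and 13 passed adjusted over the list alone. The median was 1.08 and the camera adjusted p 6.66e-10, with an adjusted p = 0.502 with an estimated correlation. The mean of the 14 genes, taken from the mean of the kept WT arrays of the chip, also varied among arrays of 1 genotype. It was 0.53 and -0.53 on WT replicates 1 and 2, 0.72 and 0.71 on KO replicates 1 and 2, and 1.68 and 0.93 on KO replicates 3 and 4. The excluded WT replicate 5 stood at 1.71 and the excluded KO replicate 5 at 0.16. Progenitor genes were not called as a list (11 measured, median 0.30, adjusted p = 0.167), but were with every gene of chip 2 on that chip alone (14 measured, median 0.58, adjusted p = 0.0156, and adjusted p = 0.766 with an estimated correlation). Slc1a3, a glutamate transporter of radial glia, fell by 1.15 (SE 0.24, adjusted p = 0.0391).

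**Figure D2:**
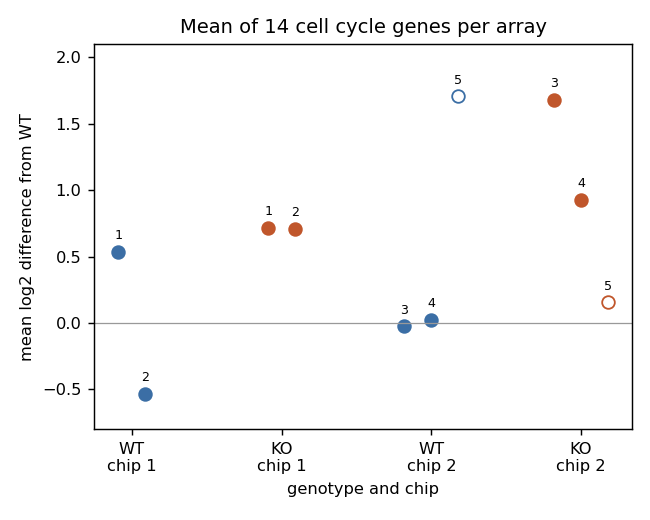
Mean log2 difference from the kept WT arrays of the same chip (vertical axis) over 14 cell cycle genes, with 1 point per array, WT in blue, KO in orange, the replicate number above each point and open points for the arrays that the labels exclude. The kept KO arrays lie between 0.71 and 1.68, and the excluded WT replicate 5 lies at 1.71.

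Axon guidance genes were shifted downwards. Of 23 measured, 4 fell and none rose at the threshold. The Slit receptor gene Robo2 fell by 2.25 (SE 0.25, adjusted p = 0.00427), the semaphorin receptor gene Plxna4 by 1.94 (SE 0.38), the ephrin gene Efna5 by 0.93 (SE 0.14) and Sema3f by 0.82 (SE 0.14). The Plxna4 probe used was detected on 1 of 4 KO arrays, and another Plxna4 probe stood at -0.11. The fall of Plxna4 thus rests on 1 dim probe. Other joined probes of Robo2 stood at -1.69, -1.49 and -0.95, and another of Sema3f at -0.42. Adjusted over the list alone, 8 were lower and 2 higher. The camera adjusted p was 0.0189, with an adjusted p = 0.370 with an estimated correlation. The list was not called without WT replicate 3 (adjusted p = 0.0669) or on chip 1 alone (adjusted p = 0.0705). Among 13 cadherins and protocadherins, Pcdh9 fell by 1.81, Pcdh19 by 1.31 and Cdh4 by 1.15, Cdh6 rose as given above, and the list was not called (adjusted p = 0.412). The fall of Pcdh9 differs by probe: another joined probe stood at -0.90, and 2 probes on chip 2 alone at 0.28 and 0.11.

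Genes of other cell types and pathways gave few calls. GABAergic and prethalamic genes had a median of -1.40 over 4 measured members with none past the threshold (list adjusted p = 0.134), as with Slc32a1, the vesicular GABA transporter gene, at -1.46 (SE 0.63). The rostral thalamus and zona limitans list had a median of -1.12 over 7 members (adjusted p = 0.151). These genes were also uneven among WT arrays, since Gad1 read 4.84 on WT replicate 1 and 8.70 on WT replicate 2. Without WT replicate 1, the GABAergic and rostral lists were called (adjusted p = 0.00151 and 0.00584), but not with an estimated correlation (adjusted p = 0.358 each). The rostral list was also called with every gene of chip 2 on that chip alone (adjusted p = 0.0297, and adjusted p = 0.778 with an estimated correlation). Of 11 pan-neuronal genes only Nefm passed the threshold, upwards, while the median was -0.23 and 2 of the 11 had positive values. Adjusted over the list alone, 2 were higher and 1 lower, and the list was not called (adjusted p = 0.351). The Wnt target Ccnd1, which encodes cyclin D1, rose by 1.44 (SE 0.29, adjusted p = 0.0350), with the list of 5 at an adjusted p of 0.151. Without WT replicate 1 that list was called upwards (adjusted p = 0.0462, and adjusted p = 0.333 with an estimated correlation). Enpp2, listed for choroid plexus and encoding autotaxin, fell by 1.77 (SE 0.22, adjusted p = 0.00684), and its list of 2 was not called (adjusted p = 0.412).

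Markers of blood, vessels, microglia and meninges did not pass the threshold. The medians were -0.21 for 6 erythroid genes (adjusted p = 0.351), -0.19 for 8 endothelial genes (adjusted p = 0.351), -0.19 for 4 microglial genes (adjusted p = 0.412) and 0.15 for 2 meningeal genes (adjusted p = 0.598). The erythroid list was called downwards on chip 1 alone (adjusted p = 0.0294) and without WT replicate 3 (adjusted p = 0.0280), though not with an estimated correlation (adjusted p = 0.681 and 0.477). Hbb-bh1, an embryonic globin, was at -0.49 (SE 0.22) and Cldn5, a tight junction gene of endothelium, at -0.55 (SE 0.30). The 6 measured pretectal and midbrain genes had a median of -0.46 (adjusted p = 0.412), with Tfap2d at -1.42 (SE 0.42) and Ebf3 at 0.84 (SE 0.26). The p53 list (6 genes, adjusted p = 0.598), the immediate early and stress list (7 genes, adjusted p = 0.770) and the Sonic hedgehog target list (3 genes, adjusted p = 0.885) were not called. The Sonic hedgehog list had a median of 0.02 and a mean of -0.67 with camera pointing down, and the stress list a median of -0.14 and a mean of 0.04 with camera pointing up. In these, Cdkn1a was at -1.01 (SE 0.27), Pdk1 at 0.51 (SE 0.17) and Nkx2-2 at -2.28 (SE 0.98). Bcl11b, the only measured telencephalic gene, was at -0.25 (SE 0.18), and no hypothalamic gene of the list was measured. The list of Y-linked genes and Xist was not called (adjusted p = 0.294), but its genes differed among single arrays: on KO replicate 3 the Y-linked Eif2s3y read 4.73, which is not above background, with Xist at 12.9, and on WT replicate 4 Eif2s3y read 11.7 with Xist at 4.81.

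**Figure D3:**
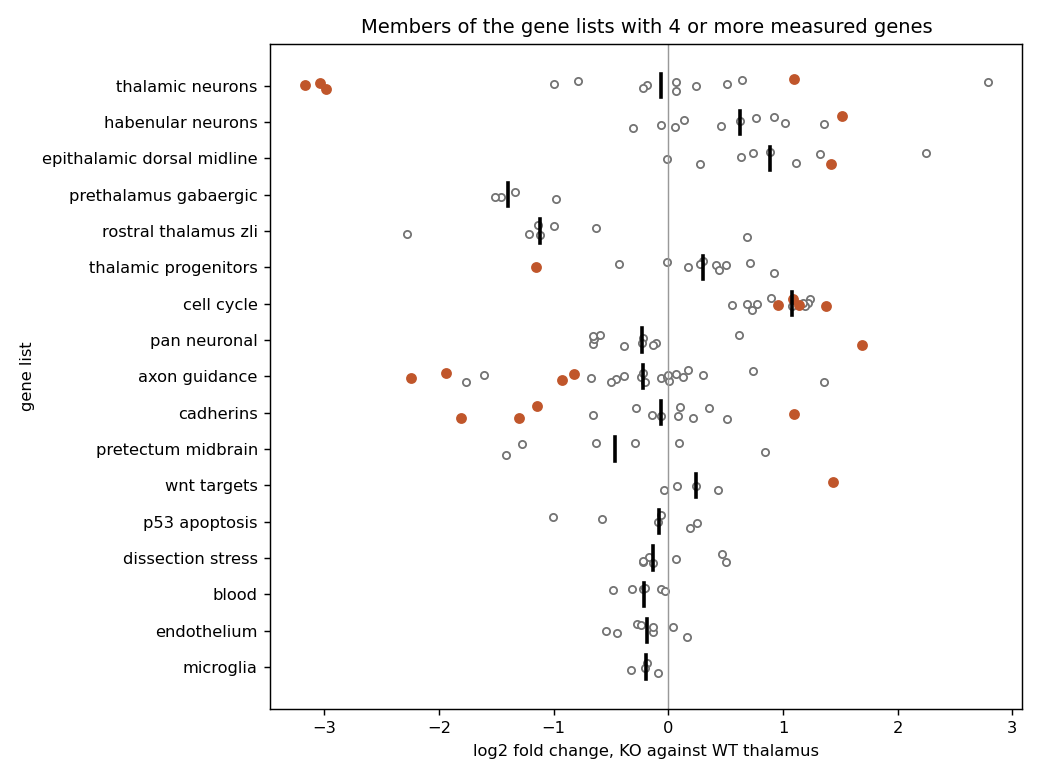
Log2 fold change of KO against WT thalamus (horizontal axis) for each measured member of the gene lists with 4 or more measured genes (vertical axis), with filled orange points past an adjusted p of 0.05, open grey points for the rest and a black bar at the median. The cell cycle list has its median at 1.08 with all 14 points above 0, and the thalamic neuron list has its median at -0.06.

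The epithalamus array differed from both WT thalamus arrays of its chip most in Gbx2, Sema5a, Chst1, Olig3 and Smoc1. Smoc1, a secreted matrix protein, was higher by 3.57 and Slc30a3, a zinc transporter, by 3.39, each being the smaller of the 2 differences in log2. Tfap2b, an AP-2 transcription factor, was at least 7.69-fold higher, and Msx1, a homeobox gene of the dorsal midline, at least 3.28-fold higher. Meis1 was higher by 3.19, Unc5b by 2.57, Tfap2d by 2.45 and Bcas1 by 2.45. On the lower side, Gbx2 stood at -6.96, the semaphorin gene Sema5a at -5.03 and the sulfotransferase gene Chst1 at -4.24. Olig3 and Cyp1b1 were below background on the epithalamus array, at least 14.2-fold and 7.83-fold lower, and Pdzrn4, Ntng1 and Syt13 stood at -3.22, -2.90 and -2.54. In all, 93 genes were higher and 69 lower by 1 or more against both WT arrays, of 9797 compared. The region has 1 array, so these differences have no replicate check, and the 2 WT arrays themselves differed by 1 or more in 739 genes.

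By list, 8 of 10 pretectal and midbrain genes were higher on the epithalamus array, as were 4 of 7 genes of rostral thalamus and zona limitans. Of 11 habenular genes 1 was higher, the nuclear receptor gene Nr4a2 at 1.61, and Gng8 at -2.35 and Etv1 at -1.07 were lower. Isl1 was at least 1.73-fold higher and Cntn2 differed by 0.69. Of 10 dorsal midline genes Msx1 was higher, with Otx2 at 0.84. Of 13 thalamic neuron genes, Zic4 was higher (2.03), and Ntng1, Rora (-1.74) and Calb2 were lower, with Lef1 and Prkcd at 0.62 and 0.59. GABAergic genes were higher against both WT arrays too, by 1.45 for Gad1, 1.17 for Slc32a1 and 1.09 for Lhx1. The latter 3 read far higher on WT replicate 2 than on WT replicate 1, with Lhx1 at 9.96 against 5.39.

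On the prethalamus array, 10 of 11 genes of the prethalamic and GABAergic list were higher than on both WT thalamus arrays. Isl1 and Meis2, homeobox genes, were at least 92.9-fold and 61.0-fold higher than on the WT thalamus arrays of the chip, and the somatostatin gene Sst was higher by 5.20. Rxfp3, a relaxin family peptide receptor gene, was at least 9.95-fold higher and Foxd1, a forkhead gene, at least 10.3-fold. Dlx6 was higher by 3.91 and Slc30a3 by 3.71, and a probe named Mrg1 in the files was higher by at least 4.32 in log2. Gbx2 stood at -5.04, the homeobox genes Shox2 and Lhx9 at -4.64 and -4.56, Sema5a at -3.66, and Syt13, Esrrb, C1ql2 and Cyp1b1 were at least 14.4-fold, 11.1-fold, 8.45-fold and 8.04-fold lower. Of 9974 genes compared, 118 were higher and 95 lower.

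Of 13 thalamic neuron genes 6 were lower on the prethalamus array, among them Slc17a6 at -3.31 and Tcf7l2, at least 4.17-fold lower, while Cdh8 was higher (1.30). Prox1 and Zic4 differed by 0.59 and 0.49. Of 8 habenular genes Isl1 was higher and Gng8 lower (-3.09), with Nr4a2 at -0.78, Cntn2 at -0.14 and Chrna3 at 0.43. None of 7 dorsal midline genes was higher or lower by 1, with Otx2 at 0.26, Wnt8b at 0.14 and Barhl2 at -0.04.

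Genes set apart by region on chip 1 were then followed in the KO on chip 2, so that no array served both steps. Genes lower in epithalamus than in WT thalamus were lower in the KO: of 69 genes, 63 had negative differences and 21 passed the test on chip 2, with a median of -1.31 against -0.05 for all genes. This set was called by camera (adjusted p = 3.91e-23, and adjusted p = 0.169 with an estimated correlation). Genes lower in prethalamus were lower as well, with 74 of 95 negative, 12 past the threshold and a median of -0.54 (adjusted p = 8.13e-09, and adjusted p = 0.169 with an estimated correlation). Of the 93 genes higher in epithalamus only 66 passed the detection filter on thalamus arrays and could be followed, and of the 118 higher in prethalamus 81, while the lower sets lost none. The genes higher in epithalamus that were followed were not shifted as a set, with 33 of 66 above 0, a median of -0.07 and an adjusted p of 0.942. Those higher in prethalamus had a median of -0.29 (adjusted p = 0.0393, and adjusted p = 0.572 with an estimated correlation). The call was lost without KO replicate 3, which leaves 1 KO array. With replicate 5 of each genotype included the set turned its direction and was not called (camera adjusted p = 0.444). Across genes, the region differences of chip 1 and the KO differences of chip 2 had a Pearson r of 0.248 for epithalamus (8982 genes) and 0.0295 for prethalamus (9047 genes), where genes are not independent replicates.

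The KO differences of the chips ran in the same direction. Across 10384 genes Pearson r was 0.588 and Spearman rho 0.481. Of the 298 changed genes, chosen by the joint fit of both chips, 254 were detected in both genotypes on both chips. Among these 218 differed more on chip 2, as with Rora at -2.19 on chip 1 and -3.78 on chip 2. Over the 298 the slope of chip 2 on chip 1 was 1.39. Col2a1 is an exception, at 2.06 on chip 1 and 1.30 on chip 2. Tested by limma, 0 genes showed an interaction of chip and genotype at an adjusted p under 0.05, and 606 did at an unadjusted p under 0.05. Chip 1 alone gave 0 genes past the adjusted threshold (1013 at an unadjusted p under 0.05) and chip 2 alone 45, of which 7 were higher and 38 lower. With replicate 5 included the correlation was 0.387.

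**Figure D4:**
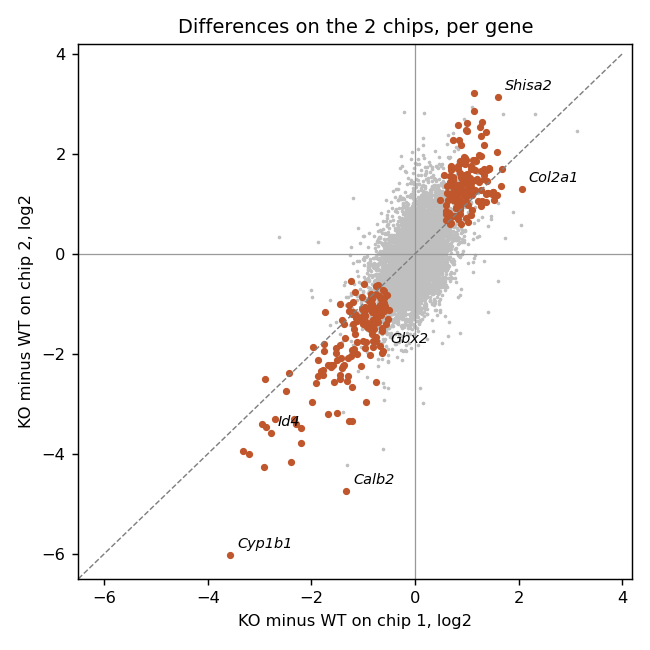
KO minus WT log2 difference on chip 1 (horizontal axis) against that on chip 2 (vertical axis), with 1 point per gene, the 298 genes past the threshold in orange, the rest in grey and a dashed line of equality. The orange points were chosen by the joint fit of both chips, and Id4 lies at -2.79 and -3.59. Cyp1b1 and Calb2 were below background on the KO arrays by the probes used. Their points use those KO values, so they are neither bounds nor measured sizes.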

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

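Of the tests below, the counts over other splits of the arrays were planned, as were the fits without KO replicate 3, with replicate 5 and with an estimated correlation over all 8 arrays. The others were chosen after the results were seen. The permutations of the cell cycle, habenular and midline means were extended from 8 to 10 arrays after the values of the excluded arrays were seen. The criteria on epithalamic tissue and on the scanner ceiling were also set after their values were seen.

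Other splits of the 8 arrays into 4 and 4, with chip as a block, were fitted for 34 of 35 splits. Only 1 of 34, the real one, gave as many genes as the 298 found, and the highest other gave 18. Only 18 of these splits hold 2 arrays of each chip on each side, as the real one does. Among them the highest other gave 0 genes, but 18 are too few for a share under 0.05, and 15 genes passed with replicate 5 of each genotype included. For the number of lists chance is not excluded: 14 of 34 splits called 4 or more lists, and the highest other called 7.

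Some arrays stood far from the other 3 of their group in values adjusted for chip, in 13 of 128 groups tested, where chance gives about 1 in 20. KO replicate 3 accounted for 6 of the 13. It was high for Ect2 (9.16, others 7.93 to 8.08), Pdlim1 (10.82, others 10.16 to 10.23), Top2a (9.40, others 8.85 to 8.88) and Pdk1 (7.14, others 6.80 to 6.85). It was low for Plxna4 (4.25, others 5.62 to 5.74) and the Y-linked gene Kdm5d (4.63, others 7.65 to 8.03). WT replicate 3 was high for Rora (10.43, others 8.69 to 8.92) and low for Hbb-bh1 (10.20, others 10.86 to 10.95), and KO replicate 4 was high for Hbb-bh1 (10.64, others 10.04 to 10.14). WT replicate 1 was high for Mcm5 (11.64, others 10.64 to 10.77) and WT replicate 2 low for Twist1 (6.22, others 6.82 to 6.91). WT replicate 4 was high for Csf1r (6.92, others 6.30 to 6.36), and KO replicate 1 low for Tfap2d (4.26, others 5.48 to 5.60).

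Probes on chip 2 without a partner on chip 1 gave 35 probes past an adjusted p of 0.05, of 6879 tested. The excluded arrays were placed on a scale from the WT (0) to the KO (1) arrays of chip 2, over the changed genes weighted by their chip 1 differences. The excluded WT replicate 5 lay at 0.880 and the excluded KO replicate 5 at 0.398. Their Cyp1b1 values were 8.83 and 6.40 in log2. Their Gbx2 values, 15.18 and 13.69, followed the labels, against 15.95 and 15.75 on the kept WT arrays and 13.75 and 14.04 on the kept KO arrays in the same normalization.

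Cell cycle genes were higher in the KO. KO replicate 3 is not the whole cause, since without it the median was 0.84 in place of 1.08 and the list was still called at the preset correlation (adjusted p = 2.48e-08). With an estimated correlation it was called neither without that array (adjusted p = 0.703) nor with all 8 (adjusted p = 0.502). If fewer neurons raised all other cell types alike, the markers of those types would rise too. The 20 markers of endothelium, blood, microglia and mesenchyme had a median of -0.19 (SD 0.204). These markers cannot test a lower share of neurons in favour of progenitors alone. Of 11 pan-neuronal genes 2 had positive values (median -0.23) and of 11 progenitor genes 8 (median 0.30), and neither list was called. A lower share of neurons thus stays open. Spread between embryos or dissections that fell with genotype by chance may account for the rise: over 10 arrays, with the excluded ones counted, an exact two-sided permutation within chips gave p = 0.233 (120 assignments), and over 8 arrays p = 0.0556, the smallest that 36 assignments allow. A change of proliferation in the KO also stays open.

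Habenular and epithalamic midline genes were higher in the KO. Over 10 arrays, with the excluded ones counted, an exact two-sided permutation within chips gave p = 0.0167 for the habenular mean (adjusted over lists, 0.117). In this exact permutation 120 assignments allow no smaller p. For the midline mean the same exact permutation gave p = 0.333 (adjusted, 0.732). Over 8 arrays the exact permutation gave p = 0.0556 for each mean, the smallest that 36 assignments allow. Spread by chance is thus not excluded for either list. Epithalamic tissue in the KO dissections is a candidate explanation, and 10 of 20 measured members were higher on both KO arrays of chip 1 than on the epithalamus array and both WT arrays. The 66 genes higher on the epithalamus array that could be followed had a median of -0.07 on chip 2, against 0.79 for the lists. Both values run against it, but with 1 epithalamus array, whose own pretectal and GABAergic genes stood high, they do not decide it. A change of identity in the KO, the question of the series, stays open and untested beside it.

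Gbx2 signal remained in the KO. WT cells or RNA in the KO samples would hold every other fall to that of Gbx2 or less. Yet 143 of 153 other fallen genes were lower than Gbx2 on chip 1, where Gbx2 stood at -0.62. The 153 were chosen by the joint fit of both chips for their falls, which raises this count, so the count alone does not decide it. Id4, Sertad4 and Ppm1h, from the largest falls, were detected on every KO array. They stood at -2.79, -2.70 and -2.96 on chip 1 and at -3.59, -3.29 and -3.39 on chip 2. Their SD within a genotype, adjusted for chip, was at most 0.71. For these genes the chip 1 sizes argue against WT cells or RNA as the whole source of the Gbx2 signal. On chip 2, 53 of the 153 were lower than Gbx2, which lay near the array maxima in WT there, so its fall may be compressed. A ceiling of the scanner could compress WT values but not lift the KO signal, which on its lowest array lay 7.33 above the lowest detected probe in log2. A probe outside the deleted part of the gene stays possible, since the tables used here hold only 1 Gbx2 probe.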

How the results depend on the processing

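Alternatives that left out WT replicate 2 and KO replicate 3 together, or took every gene of chip 2 on chip 2 alone, or joined an estimated correlation to another setting, were chosen after seeing the data, and the others were planned. No sign was reversed among 42 named genes that changed. Each of these had every KO array beyond every WT array of its chip. Only other normalizations or offsets, the deposited values and replicate 5 could thus have reversed a sign. With replicate 5 of each genotype included 6 of the 42 passed, without a filter on dim probes 18, and on chip 2 alone 19. On chip 1 alone 0 of the 42 passed, without a chip term 0, and without WT replicate 2 and KO replicate 3 14. List tests were not run with chip as a random block, and where leaving out an array of chip 2 left 1 array of a group in the set tests, that array was assumed to vary like the others. The cause of the changes given here was not tested, except that fewer arrays and more genes tested weaken a call by construction. Dim genes are limited by signal over background.

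The number of changed genes, 298, was 190 with log2 quantile values without background correction, 587 with the deposited values, 84 without a filter, 15 with replicate 5 included, 600 with chip as a random block, 583 with array weights, 45 on chip 2 alone and 43 to 612 leaving out arrays. By limma it was 0 without a chip term (74 at an unadjusted p under 0.05) and 0 on chip 1 alone (1013 at an unadjusted p under 0.05). In a check chosen after seeing the data, 68 of the 298 genes had 91 other detected joined probes, of which 64 had the same sign at an unadjusted limma p under 0.05 and 5 the opposite sign. Of the 298, 280 were among the 587 of the deposited values and 176 among the 190.

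Gbx2 kept its direction but not its call with cyclic loess (-1.15), without a filter (-1.27), with replicate 5 included (-1.33), without a chip term (-1.27), on chip 1 alone (-0.62), without WT replicate 2 and KO replicate 3 (-1.31) and in part when leaving out arrays (-1.49 to -1.08).

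The 4 called lists became 1 with detection at 0.01 on all 8 arrays, 8 without a chip term, 0 with an estimated correlation and 4 to 7 leaving out arrays. Adjusted p for the habenular list was 0.0743 without a filter, 0.603 with the strict filter and 0.324 with an estimated correlation. With replicate 5 included it was 0.000366 by camera. For the midline list it was 0.0804 with the strict filter, 0.236 with replicate 5 and 0.324 with an estimated correlation, and for the cell cycle list 0.502 with an estimated correlation. Lists not called above were called at the preset correlation in some settings: the Wnt list on chip 2 alone (0.0407) and with every probe (0.0362), and the GABAergic list on chip 2 alone (0.0221) and with every probe (0.0362). With an estimated correlation these were 0.649, 0.520, 0.717 and 0.656. With every gene of chip 2 on that chip alone, neither the GABAergic list (10 measured, adjusted p = 0.506) nor the Wnt list (8 measured, adjusted p = 0.067) was called. For axon guidance the adjusted p was 0.0605 with the strict filter, 0.0863 with every probe, 0.0705 on chip 1 alone, 0.0705 with every gene of chip 2, 0.370 with an estimated correlation and 0.00545 to 0.0669 leaving out arrays. The correlation of the chips, 0.588, was 0.494 without a filter, 0.653 with the strict filter, 0.387 with replicate 5 and 0.417 to 0.583 leaving out arrays.

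Genes higher in epithalamus, 93, were 35 with log2 quantile, 61 with offset 50, 15 at a difference of 2, 14 with a pooled spread and 172 to 344 leaving out a WT array. Genes lower, 69, were 18, 38, 12, 10 and 188 to 214, and 40 with the deposited values. Genes higher in prethalamus, 118, were 51, 77, 34, 33 and 187 to 280, and 77 with the deposited values. Genes lower, 95, were 43, 58, 28, 33 and 209 to 468, and 58 with the deposited values. With an estimated correlation the sets lower in epithalamus and in prethalamus had an adjusted p of 0.169 each, and the set higher in prethalamus 0.572. With replicate 5 that set turned its direction (0.444), and leaving out arrays gave 0.0025 to 0.527.

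With the replicate number as a block 368 genes changed, Gbx2 fell by 1.27 (adjusted p = 0.0448), and the GABAergic and rostral lists were called (adjusted p = 0.0204 each), but not with an estimated correlation as well (adjusted p = 0.589 each). Whether the numbers pair the arrays stays undecided. In values adjusted for chip, deviations of same-numbered arrays correlated at -0.405, -0.321, -0.236 and 0.065, and 0 of 4 KO arrays correlated best with their own number. That adjustment sets the chip means of WT and KO deviations opposite to each other, which lowers correlations within a chip, where same-numbered arrays lie. Deviations taken within chip correlated at -0.1075 for the same-numbered pairs of chip 1 and 0.115 for those of chip 2.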

Other observations

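All genes and tests here were picked after the results were seen. Chip 2 probes without a partner on chip 1 were tested with limma on 2 KO against 2 WT arrays: 10 probes were higher and 25 lower at an adjusted p under 0.05. Of these 35, 16 belong to genes that also have joined probes and 19 to genes that do not. In all, 1273 of the 6879 probes tested passed at an unadjusted p under 0.05. The Wnt inhibitor gene Wif1, which the habenular list holds, fell by 2.62, and the prokineticin receptor gene Prokr2 fell by 2.71. The log2 fold change was -3.56 for the neuropeptide gene Pth2. By its 2 probes Pdzrn3 fell by 3.55 and 3.33. Of the genes changed in the joint comparison, 86 had 102 further probes on chip 2 alone, of which 97 had the same sign and 72 the same sign at an unadjusted p under 0.05. Those of Calb2 and Lmo3 stood at -4.88 and 3.33, that of Robo2, below background on the KO arrays, was at least 1.06-fold lower, and those of Pcdh9 stood at 0.28 and 0.11, the opposite sign. Probes of Bub1b and Ska3 stood at 2.60 and 2.05.

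Of 43 histone genes measured in the joint comparison by 1 probe each, 11 rose and 0 fell by limma, 35 had positive values and the median was 0.65. Against 144 rises among 10384 genes, Fisher's exact test gave p = 9.77e-12, where genes that move together are not independent. Of 13 further joined probes of histone genes, 10 had the sign of the probe used and 3 the opposite one, among them 1 of H2bc21 at -0.65 against 1.20 for the probe used. All 9 further probes on chip 2 alone had the sign of the probe used, among them 1 of H2aj, which was below background on the KO arrays and at least 4.68-fold lower (adjusted p = 0.0205), with the probe used at -0.70. The excluded WT replicate 5, whose cell cycle mean stood at 1.71, was not in this comparison.

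GABAergic genes differed between arrays of 1 genotype. Gad1 read 4.84 and 8.70 on WT replicates 1 and 2, 8.66 and 9.10 on WT replicates 3 and 4, and 5.09, 6.05, 6.09 and 8.06 on KO replicates 1 to 4. The excluded WT replicate 5 read 5.86 and KO replicate 5 read 8.90. On KO replicate 4, WT replicate 3 and the excluded WT replicate 5, Xist (10.8, 10.6 and 11.6) and the Y-linked Eif2s3y (10.1, 10.9 and 9.71) were both detected.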
